A study of Mus musculus with 15 samples.

How the data were processed

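Gene expression was measured on 15 one-colour Agilent mouse arrays, each hybridised with Cy3-labelled cDNA from antigen presenting cells of the small-intestinal lamina propria of male mice. Per the labels, the cells were sorted by flow cytometry as MHC class II positive cells without CD19 or T cell receptor, and their RNA was amplified with the Miltenyi SuperAmp procedure, whose details the supplier does not disclose. The samples fall into 3 groups of 5: control mice on normal diet, mice after 10 days on a high-fat diet and mice after 30 days on it. The labels do not say that the 5 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

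The scanner files hold linear intensity values, written by Agilent Feature Extraction 10.7.3.1 per the file headers. Per the file headers, background was taken from negative control spots after spatial detrending, and low signals were replaced by a surrogate value. Surrogates made up 23.0% to 44.8% of the spots of an array, 110 to 188 spots per array were marked as outliers and 0 were saturated. The deposited series table holds log2 values, and a comparison of each column with its own array gave a Spearman correlation of 0.996 to 0.999 over the values present. Its columns hold 15889 to 30457 values each with a median of 5.52. Their 1st to 99th percentiles, over 7 percentiles compared, differed between columns by at most 0.00037, as on a quantile-normalized scale. How the deposited table was filtered is not given in the sources used here. At least 99.96% of its values in each column belonged to probes called well above background on that array. It was used only as an alternative.

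Each array carried 62976 spots, of which 59305 were not controls, for 55681 probes. Control spots and outlier spots were left out and the spots of a probe were averaged. A probe counted as detected on an array where at least 50 percent of its spots were well above background. Fewer than 50 percent of the probes were detected on most arrays, so the log2 processed signal of each array was scaled to the 75th percentile of the 8425 probes detected on all 15 arrays, and the mean of these percentiles over arrays was added back. This scaled log2 signal is the level printed for a gene. Gene names came from a name table of assembly GRCm38.p6, through RefSeq accessions for 27509 probes, a current symbol for 3549 and a unique synonym for 404. The name in the file was kept for 1808 probes, and 22411 without a gene name stood for themselves. A gene was represented by its probe with the highest mean over all arrays. It was tested if detected on at least 3 arrays of a group, which kept 26949 probes and 23732 genes, 12612 of them named. Positions are those of the probes in the file headers' build mm9, 1-based. The array carries no exon annotation in the files used here, so positions are given without it.

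Apart from the choice of probes for the main scaling, the design, the alternatives and the gene lists were fixed before the data were examined. The probes for that scaling were chosen after the share of detected probes was seen. Group means were fitted over all 15 arrays with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with statmod 1.5.0 and data.table (version 1.17.8). Contrasts were day 10 minus control, day 30 minus control and day 30 minus day 10, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All limma tests were two-sided. Errors of log2 changes are the moderated standard errors of limma. A gene not detected on any array of a group has only a bound there, given as "at least N-fold". The bound sets the mean of the brighter group against the mean, over the arrays of the dim group, of the higher of the array's lowest detected signal and the probe's own signal. It applies to the measured means and leaves out sampling error. For genes that did not pass it is therefore no lower limit of the true change.

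For each contrast the text names the genes past the threshold with a gene symbol whose brighter group was detected on all 5 arrays. Up to 10 in each direction are named. Where fewer than 5 passed in a direction, the 5 with the smallest p are named as not past it. In each list described, up to 4 members with the smallest p are named, together with members past the threshold when adjusted over the list alone. Gm1976 passed the threshold but fell outside the rule because of its kind of name, and Epcam, Fabp1, Lct, Apoc3, Ccr2, Tgfb1, Cd19 and the most abundant transcripts of other cell types were chosen after their values were seen. A fixed panel of 30 genes for cytokines, costimulation, antigen presentation and microbial sensing was summarised.

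Gene lists were tested with camera of limma, two-sided, at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 35 lists. An estimated correlation and fry were alternatives, and fry was also run under 4 other scalings, chosen after seeing the data. A list needed 5 measured members. The shift of a list is the median log2 change of its members minus that of all genes. The score of a list on an array is the mean signal of its members minus the median signal of all genes on that array. The cell type lists covered conventional dendritic cells, intestinal macrophages, monocytes and neutrophils, plasmacytoid dendritic cells, B cells and plasma cells, T cells, innate lymphoid and NK cells, enterocytes, secretory epithelium, and stromal, endothelial and muscle cells. The immune lists covered MHC class II and class I presentation, costimulation, T cell polarizing (Th17-inducing) cytokines, inflammatory cytokines and chemokines, anti-inflammatory genes, microbial pattern recognition, NF-kB and immediate early genes, interferon-stimulated genes and antimicrobial peptides. The metabolic and stress lists covered fatty acid oxidation, lipid uptake and storage, cholesterol synthesis, LXR targets, glycolysis, oxidative phosphorylation, the unfolded protein response, oxidative stress (NRF2 targets), heat shock, cell cycle, lysosome and phagocytosis, the circadian clock, insulin and leptin signalling, ribosomal proteins and mitochondrially encoded genes. Lists of mast cells, eosinophils and basophils (4 of 17 genes measured), red blood cells (2 of 10) and genes for a check of sex (3 of 5) were too small to test.

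The arrays came from 3 slides. Control 1 was alone on the first, controls 2 to 5 and day 10 arrays 1 to 4 shared the second, and day 10 array 5 and the 5 day 30 arrays shared the third. Day 10 and control could therefore be compared within the second slide, and day 30 and day 10 within the third with 1 array against 5. No slide held both control and day 30 arrays.

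Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, scaling to the median, no filter on dim probes, a filter to probes detected on all 15 arrays, the mean over a gene's probes, slide as a fixed or random block, fits within a slide, the replicate number as a block, the compared groups alone, array weights, a trended robust variance, the deposited series table, unadjusted p, a fold minimum and leaving out each array in turn. Scaling over all probes, cyclic loess, the share of detected probes as a covariate, leaving out the 3 arrays farthest from the median detection and 10000 random lists matched on signal were added after seeing the data. No pair of arrays held identical values, and correlations between arrays over genes lay between 0.533 and 0.699.

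The procedure was tested on simulated data built from these arrays. Among 23708 genes, with 66 or 67 genes changed at each size, a log2 change of 2 was recovered for 2.99% at day 10 and 2.99% at day 30, a change of 4 for 23.9% and 26.9%, and a change of 6 for 59.1% and 57.6%. For day 30 minus control, a shift of 1.5 put into the 19 measured genes of cholesterol synthesis was called with an adjusted p of 0.0017, and 0 of the other lists was called. The genes were simulated independently of each other, so this cannot show how often the list test calls lists by chance on the real arrays. There, other splits of the control and day 30 arrays gave a median of 3 lists called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.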

Results

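Antigen presenting cells take up antigen and display it to T cells. Those of the intestinal lamina propria lie beneath the epithelium that faces the gut microbes. The study fed mice a high-fat diet to change these microbes and profiled the cells after 10 and 30 days, in stages its title calls prediabetic and diabetic. Cells of mice on normal diet were the controls, with 5 arrays per group and 15 in all. Genes of MHC class II molecules, which mark the sorted cells, gave strong signals. H2-Ab1 had a scaled log2 signal of 14.34 ± 0.69 in controls, 14.89 ± 0.19 at day 10 and 15.26 ± 0.18 at day 30 (SD, n = 5 each). Cd74, the invariant chain, had one of 15.64 ± 0.27, 15.89 ± 0.11 and 16.04 ± 0.24. Transcripts of antibody-secreting cells, which can lack the CD19 that the sort excluded, were present too. Jchain, the joining chain of secreted IgA, had a signal of 15.57 ± 0.26 in controls, 14.18 ± 0.39 at day 10 and 14.24 ± 0.93 at day 30. All 3 genes were detected on all 15 arrays.

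The arrays differed in how many of their 55681 probes were well above background. The share was 43.3% ± 6.77 (range 35.8% to 51.4%) in controls, 44.1% ± 9.92 (35.4% to 59.9%) at day 10 and 37.3% ± 5.63 (31.1% to 46.4%) at day 30 (SD, n = 5 each). No difference between groups passed an exact two-sided permutation test over 252 divisions. Day 10 minus control was 0.83 points (exact p = 0.841, adjusted over 3 comparisons 0.841). Day 30 minus control was −5.96 points (exact p = 0.183, adjusted 0.286), and day 30 minus day 10 was −6.79 points (exact p = 0.191, adjusted 0.286). The first principal component held 20.6% of the variance and went with the share of detected probes over the 15 arrays (Pearson r = 0.861, permutation p = 3e-05; Spearman rho = 0.804, permutation p = 0.00047). This was the only such relation tested. Without the 2 arrays farthest from the median detection, r was 0.834. It was 0.937 within the slide of 8 arrays and 0.754 within that of 6.

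**Figure D1:**
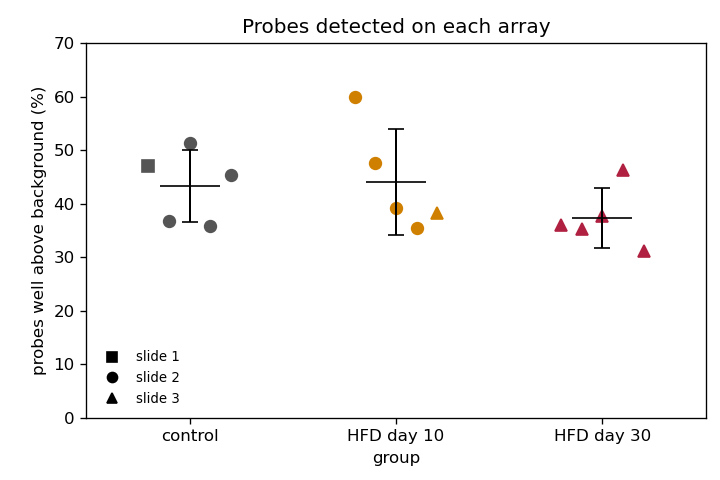
Share of probes well above background (%, vertical axis) on each array of the 3 groups (horizontal axis); symbols give the slide, long bars the mean and whiskers the SD over 5 arrays. Group means lie at 43.3%, 44.1% and 37.3%, and the arrays of the groups overlap.

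The first comparison asked which transcripts differed after 10 days of high-fat diet. Bcar3, an adaptor protein that binds the scaffold p130Cas, fell from a log2 signal of 8.95 ± 1.68 in controls to 1.71 ± 0.43 at day 10 (SD, n = 5 each). The log2 change was −7.24 ± 0.69 (SE; adjusted p = 0.00106), at least 36.2-fold. All 5 day 10 arrays lay below all 5 controls and were not well above background. Wdr55, a WD repeat protein that takes part in ribosomal RNA processing, rose from 2.92 ± 1.55 to 9.59 ± 1.34, a log2 change of 6.67 ± 0.81 (adjusted p = 0.0103). Ryr1, a calcium release channel known from skeletal muscle, rose from 2.75 ± 0.96 to 9.24 ± 2.08, a log2 change of 6.50 ± 0.90 (adjusted p = 0.0326). For both genes all 5 day 10 arrays lay above all 5 controls, of which 1 was well above background. The predicted gene Gm1976 rose by 5.17 ± 0.74 on the log2 scale, at least 14.4-fold (adjusted p = 0.0337). It was detected on all 5 day 10 arrays and on 0 of the others; its second probe was not detected on any array. Bcar3 was probed at chromosome 3, 122232748 to 122232807, and Wdr55 at chromosome 18, 36923119 to 36923178. Ryr1 was probed at chromosome 7, 29788789 to 29789487, and Gm1976 at chromosome 17, 95214328 to 95214387. Limma called these 4 genes, 3 higher and 1 lower, among 23732. At an unadjusted p under 0.05 there were 1441, of which 48.9% were higher.

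Other named genes did not pass at day 10. Gpnmb, a transmembrane glycoprotein of macrophages and other phagocytes, had a log2 change of 7.37 ± 1.18 (adjusted p = 0.0882). Stra6l, a receptor for retinol-binding protein, had one of 6.07 ± 1.23 (adjusted p = 0.463), and Rpf2, a ribosome assembly factor, one of 5.39 ± 1.07 (adjusted p = 0.439). On the lower side, the collagen gene Col28a1 was detected on 5 control arrays and on 0 at day 10 (log2 change −4.18 ± 0.74, at least 7.47-fold, adjusted p = 0.208). S1pr1, a receptor that guides lymphocyte egress, had a change of −4.98 ± 1.04 (adjusted p = 0.463). Stoml1, a stomatin-like membrane protein, had one of −5.23 ± 1.11 (adjusted p = 0.463), and the olfactory receptor gene Olfr1030 one of −4.02 ± 0.99 (adjusted p = 0.508). The probes of Stra6l, Rpf2 and Col28a1 lie at chromosome 4, 45899817 to 45899876, chromosome 10, 39943490 to 39943549, and chromosome 6, 7947808 to 7947867. Those of S1pr1, Stoml1 and Olfr1030 lie at chromosome 3, 115414020 to 115414079, chromosome 9, 58110001 to 58110060, and chromosome 2, 85824560 to 85824619.

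With slide as a block, the day 10 changes were −7.33 for Bcar3 (adjusted p = 0.00833), 6.67 for Wdr55 (0.0917), 6.47 for Ryr1 (0.191), 6.36 for Gm1976 (0.00014) and 7.54 for Gpnmb (0.0940). Only the slide that held 4 controls and 4 day 10 arrays informs these blocked changes. A fit within that slide gives the same changes by design, so it is no second check. Its adjusted p for Bcar3, Wdr55, Ryr1, Gm1976 and Gpnmb were 0.0707, 0.191, 0.256, 0.0122 and 0.235. Ryr1 lost its call in 10 of the 15 fits that left out 1 array (adjusted p = 0.052 to 0.117). Limma called 0 genes at day 10 when the 2 groups were fitted alone or after normexp with quantile normalization. The count of 4 genes was 7 without control 5 and 2 without day 10 array 3, day 30 array 3 or day 30 array 4.

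Gene lists were read against the median change of all genes. On the log2 scale this median was −0.16 at day 10, −0.60 at day 30 and −0.44 from day 10 to day 30. It followed the scaling, being −0.02, 0.04 and 0.03 after quantile normalization and −0.04, 0.28 and 0.33 with scaling over all probes. At day 10, 4 of 35 lists rose by camera, and no member of any list passed over all genes. Genes of the lysosome and phagocytosis shifted by 1.47 relative to all genes (42 genes, 35 above the all-gene median, adjusted p = 8.26e-06). Their adjusted p = 0.0765 with an estimated correlation. At an unadjusted p under 0.05, 7 were higher and 1 lower, and when adjusted over the list alone 0 rose and 0 fell. They included Grn, the progranulin gene (log2 change 4.65 ± 1.52), the glycosidases Gla (1.40 ± 0.53) and Hexb (4.44 ± 1.71), and the receptor tyrosine kinase Tyro3 (−1.82 ± 0.64). NF-kB and immediate early genes, which respond within minutes to hours to stimulation, shifted by 0.92 (36 genes, 29 above the all-gene median, adjusted p = 6.08e-05). Here adjusted p = 0.117 with an estimated correlation. Unadjusted, 3 were higher and 0 lower, namely Traf1 (2.40 ± 0.73), Egr1 (1.67 ± 0.53) and Fosb (2.12 ± 0.91). When adjusted over the list alone 0 of the 36 passed.

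Cholesterol synthesis genes shifted by 1.16 at day 10 (19 genes, 16 above the all-gene median, adjusted p = 0.00161; adjusted p = 0.0532 with an estimated correlation). When adjusted over the list alone, 2 rose, 0 fell and 17 did not pass. These were Sc5d, a sterol desaturase (5.88 ± 1.48, adjusted p = 0.0258), and Msmo1, a sterol demethylase (5.61 ± 1.64, adjusted p = 0.0377). Hmgcs1, which makes HMG-CoA, had a change of 2.88 ± 0.97. Genes of oxidative stress and NRF2 targets shifted by 1.06 (28 genes, 20 above the all-gene median, adjusted p = 0.0421; adjusted p = 0.0929 with an estimated correlation). Adjusted over that list alone, 1 rose and 0 fell: Sod1, the cytosolic superoxide dismutase, was higher by 3.99 ± 0.90 (adjusted p = 0.0156). The peroxiredoxin gene Prdx6 stood at −4.11 ± 1.18. With slide as a block the shifts of these 4 lists were 0.70, 0.44, 0.90 and 0.49 (adjusted p = 0.0660, 0.249, 0.249 and 0.489). Within the shared slide, whose arrays alone set the blocked gene changes, they were 0.71, 0.44, 0.90 and 0.49 (adjusted p = 0.109, 0.371, 0.312 and 0.525).

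The other 31 lists were not called at day 10. The nearest were B cells and plasma cells, with a shift of −0.63, and ribosomal proteins, with one of 0.27 (adjusted p = 0.0578 for each). Among monocyte and neutrophil genes, Ccr2, the chemokine receptor of inflammatory monocytes, changed by −4.92 ± 1.23 when adjusted over the list alone (adjusted p = 0.0113). For inflammatory cytokines the shift was −0.02 while the test pointed up. For costimulation the mean change was −0.04 with a shift of 0.70. The count of 4 lists was 9 without control 2, 4 or 5 or day 10 array 2, and 11 without day 10 array 1.

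The second comparison asked the same of cells after 30 days of high-fat diet. Gpnmb rose from 2.28 ± 1.64 in controls to 11.06 ± 0.51 (SD, n = 5 each), a log2 change of 8.78 ± 1.18 (SE; adjusted p = 0.0315). All 5 day 30 arrays lay above all 5 controls, and the probe lies at chromosome 6, 49006386 to 49006445. Bcar3 fell to 1.88 ± 0.49, a log2 change of −7.07 ± 0.69 and at least 41.6-fold (adjusted p = 0.00143). It was not well above background on any of the 5 arrays. Areg, the EGF receptor ligand amphiregulin, had the largest change of the named genes that did not pass, −8.09 ± 1.42 (adjusted p = 0.114; chromosome 5, 91570090 to 91570149). Its signal was 10.62 ± 0.66 in controls, 7.31 ± 3.51 at day 10 and 2.54 ± 2.09 at day 30. Limma called 2 genes among 23732, Gpnmb and Bcar3. At an unadjusted p under 0.05 there were 2903, of which 19.2% were higher. That split was 61.6% with scaling over all probes, 29.9% with scaling to the median and 51.0% after quantile normalization.

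**Figure D2:**
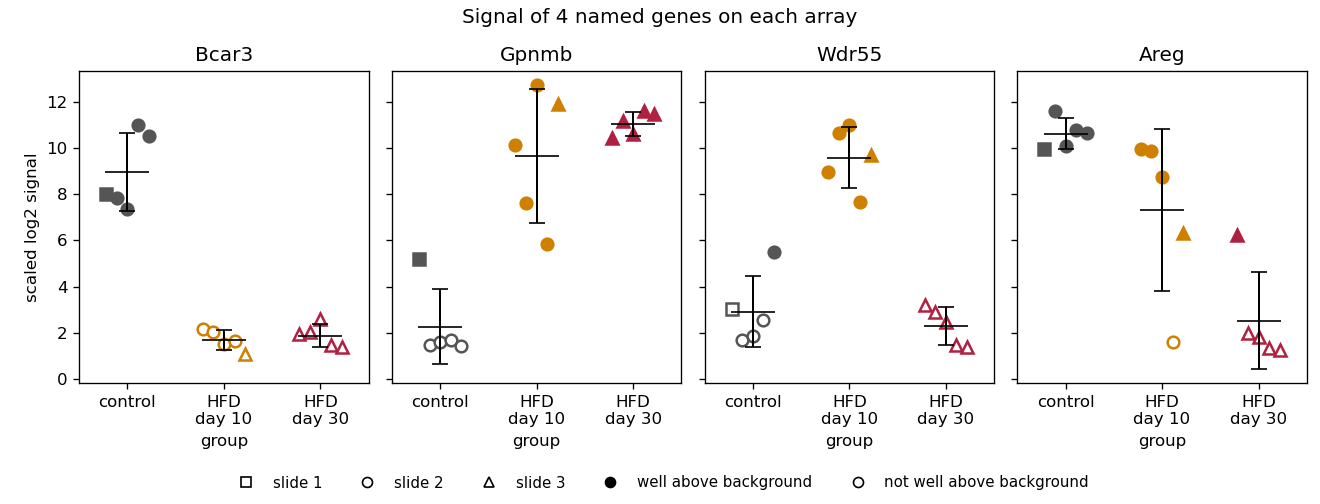
Scaled log2 signal (vertical axis) of Bcar3, Gpnmb, Wdr55 and Areg on each array of the 3 groups (horizontal axis); filled symbols are well above background, shapes give the slide, long bars the mean and whiskers the SD over 5 arrays. Bcar3 lies at 7.35 or above in controls and at 2.58 or below on all high-fat diet arrays, while Areg at day 30 holds 4 arrays at or below 2.00 and 1 at 6.24.

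Further named genes did not pass at day 30. Stra6l had a log2 change of 7.17 ± 1.23 (adjusted p = 0.114) and Sod1 one of 4.99 ± 0.90 (adjusted p = 0.117; chromosome 16, 90226509 to 90226568). Il6st, the gp130 receptor subunit shared by interleukin 6 and its relatives, had one of 6.68 ± 1.34 (adjusted p = 0.198; chromosome 13, 113296586 to 113296645). The histone acetyltransferase gene Hat1 had one of 5.52 ± 1.14 (adjusted p = 0.205; chromosome 2, 71259747 to 71272121), against −1.22 for its second probe. Lower without passing were S1pr1 (−6.80 ± 1.04, at least 28.2-fold, adjusted p = 0.0945), Col28a1 (−4.43 ± 0.74, at least 8.36-fold, 0.114) and Stoml1 (−6.09 ± 1.11, at least 15.3-fold, 0.117). S1pr1, Col28a1 and Stoml1 were detected on all 5 controls and on 0 arrays at day 30.

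No slide held both control and day 30 arrays, so this contrast rests on comparisons between slides. With slide as a block, joined only through the day 10 arrays, the change was 6.68 for Gpnmb (adjusted p = 0.905), −6.54 for Bcar3 (0.464), −7.03 for Areg, 2.70 for Il6st, −2.56 for Col28a1 and −3.60 for Stoml1. In that fit and after normexp with quantile normalization limma called 0 genes, and 10 when the 2 groups were fitted alone. Gpnmb lost its call in 7 of the 15 fits that left out 1 array (adjusted p = 0.0519 to 0.117). The count of 2 genes was 4, 13 and 10 without controls 2, 4 and 5, 10 without day 30 array 5, and 1 without day 10 array 1 or day 30 array 3.

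At day 30, 19 of 35 lists rose relative to all genes and 1 fell, again with 0 members past the threshold over all genes. No called list turned its direction under the other 5 scalings. NF-kB and immediate early genes shifted by 1.55 (36 genes, 33 above the all-gene median, adjusted p = 5.58e-11; adjusted p = 0.00672 with an estimated correlation). Unadjusted, 6 were higher and 0 lower, led by Traf1 (2.74 ± 0.73), Egr1 (1.74 ± 0.53), Fosb (2.85 ± 0.91) and Klf6 (1.27 ± 0.47). Heat shock and dissociation stress genes, of which 7 of 19 are among these 36, shifted with them by 1.01 (adjusted p = 0.000597; adjusted p = 0.0982 with an estimated correlation). Lysosome and phagocytosis genes shifted by 1.37 (42 genes, 33 above, adjusted p = 2.58e-09; adjusted p = 0.00672 with an estimated correlation), with 10 higher and 1 lower unadjusted. MHC class II presentation genes shifted by 1.17 (18 genes, 13 above, adjusted p = 0.000597; adjusted p = 0.00748 with an estimated correlation), with 5 higher and 0 lower unadjusted. Among them were the lysosomal proteases Lgmn (2.05 ± 0.71), Ctsb (1.70 ± 0.60), Ctsl (3.90 ± 1.47) and Ctss (2.19 ± 0.90), which process antigen and the invariant chain. Ctsb, Ctsl and Ctss are the 3 genes that this list shares with the lysosome list. Of the class II molecules themselves, H2-Ab1 had a change of 0.92 ± 0.42, H2-Eb1 of 0.73 ± 0.55, Cd74 of 0.40 ± 0.36 and H2-Aa of −0.02 ± 0.39. MHC class I presentation shifted by 0.96 (20 genes, 16 above, adjusted p = 0.000974; adjusted p = 0.0287 with an estimated correlation). Cd1d1, which presents lipids, stood at 3.54 ± 1.53 and H2-Q1 at −3.46 ± 1.48. When adjusted over the list alone, 0 members of these 4 lists rose or fell.

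Sterol handling genes shifted as well at day 30. LXR targets and cholesterol efflux genes shifted by 2.25 (15 genes, 14 above the all-gene median, adjusted p = 3.05e-05; adjusted p = 0.00748 with an estimated correlation). Unadjusted, 4 were higher and 0 lower: Arl4c (3.18 ± 0.98), Apoe (2.42 ± 0.78), Mertk (4.19 ± 1.53) and Scd2 (2.23 ± 0.87). None of the 15 passed over the list alone. Cholesterol synthesis genes shifted by 1.85 (19 genes, 16 above, adjusted p = 9.48e-06; adjusted p = 0.00565 with an estimated correlation). When adjusted over the list alone, 3 rose, 0 fell and 16 did not pass. Those were Hmgcs1 (3.70 ± 0.97, adjusted p = 0.0338), the sterol demethylase gene Cyp51 (4.66 ± 1.48, adjusted p = 0.0438) and Sc5d (4.67 ± 1.48, adjusted p = 0.0438). Fatty acid oxidation genes shifted by 1.39 (16 genes, 13 above, adjusted p = 0.0117; adjusted p = 0.0369 with an estimated correlation), yet over the list alone 0 rose and 2 fell. Hadhb (−4.21 ± 1.16, adjusted p = 0.0418) and Acadvl (−3.97 ± 1.22, at least 5.98-fold, adjusted p = 0.0443) are enzymes of mitochondrial beta-oxidation, as is Acadl, which stood at 4.06 ± 1.55. Lipid uptake and storage genes shifted by 0.68 (25 genes, 19 above, adjusted p = 0.00336; adjusted p = 0.0982 with an estimated correlation), with 0 past over the list alone. The LDL receptor gene Ldlr stood at 3.74 ± 1.75 and the lysosomal lipase gene Lipa at 3.31 ± 1.71.

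Among immune lists, anti-inflammatory and tolerance genes shifted by 0.89 at day 30 (22 genes, 18 above, adjusted p = 7.32e-05; adjusted p = 0.00565 with an estimated correlation). Unadjusted, 4 were higher and 0 lower, among them Hmox1 (2.95 ± 1.36) and Nfkbiz (3.07 ± 1.32). Inflammatory cytokines and chemokines shifted by 0.60 (20 genes, 14 above, adjusted p = 0.0294; adjusted p = 0.0534 with an estimated correlation). The chemokines Ccl22 (4.18 ± 1.81) and Ccl3 (3.01 ± 1.30) were higher and Cxcl3 (−4.08 ± 1.63) lower unadjusted. Before this list was set against all genes, its median change was −0.00 and its mean −0.02. Microbial pattern recognition shifted by 0.57 (32 genes, 22 above, adjusted p = 0.0145; adjusted p = 0.136 with an estimated correlation), with a median change of −0.03. The fungal receptor gene Clec7a stood at 1.63 ± 0.63, the inflammasome sensor gene Nlrc4 at 4.64 ± 1.89 and the viral RNA sensor gene Ifih1 at −3.35 ± 1.38. When adjusted over the list alone, 0 members of these 3 lists rose or fell. Among T cell polarizing cytokines, Tgfb1 rose by 4.56 ± 1.29, at least 8.62-fold, when adjusted over the list alone (adjusted p = 0.0455). It was detected on 4 day 30 arrays and on 0 controls.

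Oxidative stress and NRF2 targets shifted by 0.99 (28 genes, 20 above, adjusted p = 7.32e-05; adjusted p = 0.00565 with an estimated correlation). Sod1 rose over the list alone (adjusted p = 0.00194), and the metallothionein gene Mt1 stood at 1.88 ± 0.58. Ribosomal proteins shifted by 0.91 (66 genes, 64 above the all-gene median, adjusted p = 1.56e-08; adjusted p = 0.0528 with an estimated correlation). The shift of this bright list was 0.40 after quantile normalization and 0.35 after loess, with the call kept. Random lists matched on signal had a median change of −0.04, against −0.60 for all genes. Fau (2.30 ± 0.80) and Rps27 (1.15 ± 0.49) were higher unadjusted. Of the 19 heat shock and dissociation stress genes 16 lay above the all-gene median, although the cochaperone gene Dnajb1 stood at −4.25 ± 1.87. Insulin and leptin signalling shifted by 1.06 (22 genes, 17 above, adjusted p = 0.00336; adjusted p = 0.0522 with an estimated correlation). The adiponectin receptor gene Adipor1 stood at 1.49 ± 0.57, Rptor at 3.82 ± 1.64 and Pik3ca at −4.99 ± 2.19. Glycolysis and hypoxia response genes shifted by 0.74 (25 genes, 19 above, adjusted p = 0.00352; adjusted p = 0.0160 with an estimated correlation). The glucose transporter gene Slc2a1 stood at 3.42 ± 1.29 and Pgam1 at 3.75 ± 1.40. Oxidative phosphorylation shifted by 0.96 (44 genes, 31 above, adjusted p = 0.00381; adjusted p = 0.0982 with an estimated correlation). Unadjusted, 2 of its members were higher and 2 lower, such as Uqcrh (4.19 ± 1.46) and Ndufa1 (−5.60 ± 1.81). Apart from Sod1, 0 members of these 6 lists passed over the list alone.

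Markers of cell types inside the gate differed as well. Conventional dendritic cell genes shifted by 1.97 (23 genes, 19 above, adjusted p = 3.05e-05; adjusted p = 0.0155 with an estimated correlation). Unadjusted, 4 were higher and 0 lower, among them Wdfy4 (1.37 ± 0.45), Kit (2.80 ± 1.16) and Cd209a (4.32 ± 1.88, at least 4.50-fold, detected on 0 controls). Intestinal macrophage genes shifted by 1.97 too (19 genes, 13 above, adjusted p = 0.000974; adjusted p = 0.0274 with an estimated correlation). The complement genes C1qa (5.91 ± 1.78) and C1qb (3.53 ± 1.46) were among 4 higher and 0 lower unadjusted. With probes well above background on all 15 arrays alone, the macrophage test turned, with a shift of −0.70. Of both lists, 0 members passed over the list alone.

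Lists for lymphoid cells and enterocytes were tested alongside. Innate lymphoid and NK cell genes fell by camera, with a shift of −1.01 at day 30 (15 genes, 4 above the all-gene median, adjusted p = 0.0110; adjusted p = 0.105 with an estimated correlation). Unadjusted, 0 were higher and 5 lower. Areg, held by the list for type 2 innate lymphoid cells, fell when adjusted over the list alone (adjusted p = 0.000791). Klrb1b (−5.20 ± 1.90), Il22 (−3.39 ± 1.46) and Rorc (−2.31 ± 1.08) did not pass. Fry, which does not set a list against other genes, called this list lower too (adjusted p = 0.0206), under the scaling that puts the median of all genes at −0.60. B cell and plasma cell genes were not called by camera (shift −0.43, adjusted p = 0.0614; adjusted p = 0.171 with an estimated correlation), with 0 higher and 6 lower unadjusted. By fry they were called lower under that scaling (adjusted p = 0.0206). After quantile normalization fry gave an adjusted p of 0.0340 for innate lymphoid and 0.0316 for B cell genes, and with scaling over all probes of 0.209 and 0.580. Pou2af1 fell over the list alone (−4.77 ± 1.27, adjusted p = 0.0397). Cd19, which the gate excludes, was detected on 3 control arrays, 2 at day 10 and 0 at day 30. Enterocyte genes were not called by camera (shift 0.07, adjusted p = 0.209), with 3 higher and 2 lower unadjusted. Epcam, an epithelial adhesion molecule, rose when adjusted over that list alone (6.23 ± 1.33, adjusted p = 0.00473) and was detected on 2 controls and on all 10 high-fat diet arrays. Fabp1, the enterocyte fatty acid binding protein, had a change of 5.25 ± 1.94 (adjusted p = 0.0785 over the list alone). The lactase gene Lct (−2.73 ± 0.88, at least 1.87-fold, detected on 3 controls and 0 day 30 arrays) and the apolipoprotein gene Apoc3 (−2.95 ± 1.28) were the 2 lower and did not pass over the list alone.

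The remaining lists were not called at day 30. The shift was 0.40 for interferon-stimulated genes (adjusted p = 0.0859), 0.45 for costimulation (0.212), −0.41 for plasmacytoid dendritic cells (0.212), 0.28 for the unfolded protein response (0.403) and 0.74 for antimicrobial peptides (0.414). It was 0.53 for the circadian clock (adjusted p = 0.463), −0.62 for monocytes and neutrophils (0.516), 0.31 for T cells (0.8) and −0.06 for stromal, endothelial and muscle cells (0.903). Shift and test differed in sign for T cell polarizing cytokines (−0.11, 0.267), mitochondrially encoded genes (0.30, 0.579), secretory epithelium (0.10, 0.606) and cell cycle (−0.18, 0.853).

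With slide as a block, camera called 0 lists at day 30, against 21 at an unadjusted p under 0.05 without the block and 7 by fry, of which 6 were among the 20. The median shift of the 19 lists that rose went from 1.01 to 0.297. The shift stayed above 0 for lysosome (0.56), LXR targets (0.50), cholesterol synthesis (0.30), lipid uptake (0.92), fatty acid oxidation (1.18) and oxidative phosphorylation (1.30). It also did for dendritic cells (0.68), macrophages (0.60), anti-inflammatory genes (1.04), inflammatory cytokines (0.33) and pattern recognition (0.10). It lay below 0 for NF-kB and immediate early genes (−0.17), ribosomal proteins (−0.40), heat shock (−0.52), class I (−0.62) and class II presentation (−0.05). The same held for oxidative stress (−0.29), glycolysis (−0.29) and insulin signalling (−0.11), and innate lymphoid genes stood at −0.12. After quantile normalization 13 of the 19 remained called. Class I presentation, glycolysis, oxidative phosphorylation, fatty acid oxidation, pattern recognition and inflammatory cytokines did not. Of those that remained, the shift was 0.76 for lysosome, 0.71 for class II presentation and 0.43 for anti-inflammatory genes.

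**Figure D3:**
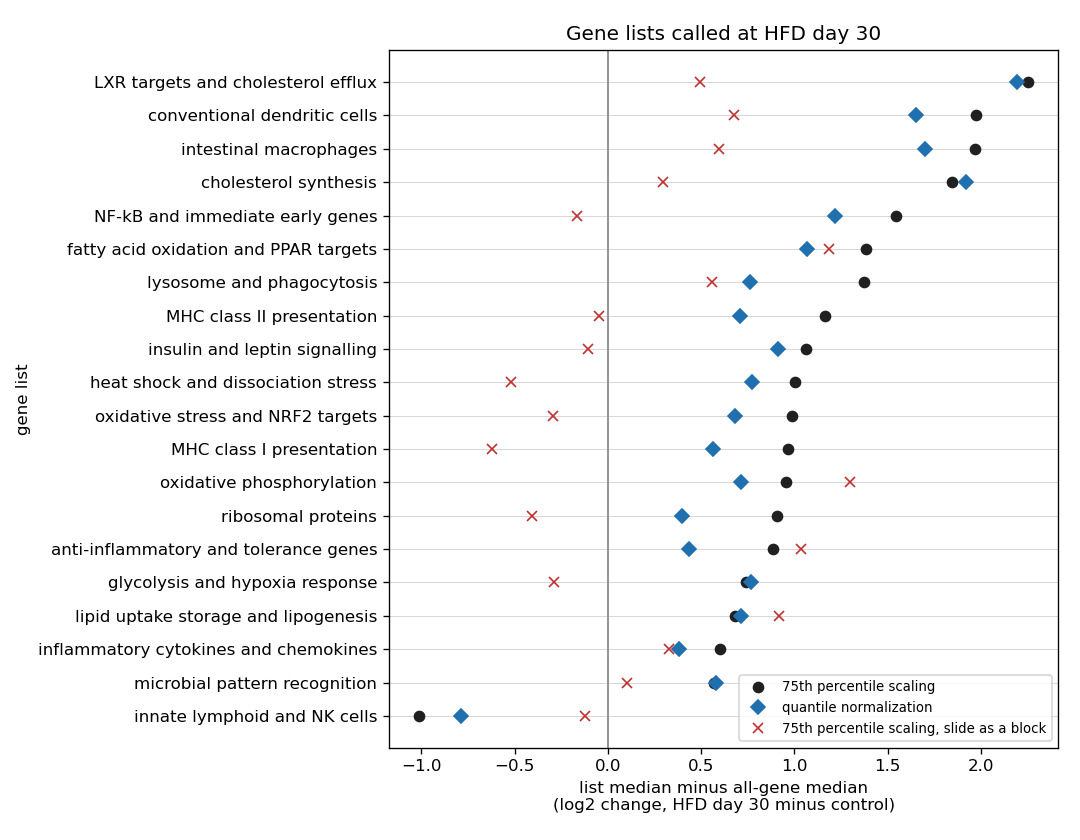
Shift of the 20 gene lists called at day 30 (vertical axis), as the list's median log2 change minus that of all genes, day 30 minus control (horizontal axis). Circles are the main scaling, diamonds quantile normalization and crosses the main scaling with slide as a block, under which 0 lists were called and the shift of innate lymphoid and NK cell genes was −0.12 in place of −1.01.

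The third comparison set day 30 against day 10. Wdr55, higher at day 10, fell to 2.29 ± 0.82 at day 30, a log2 change of −7.30 ± 0.81 and at least 63.6-fold (adjusted p = 0.00689). All 5 day 30 arrays lay below all 5 of day 10. Gm1976 fell by 5.97 ± 0.74, at least 19.8-fold (adjusted p = 0.0129), likewise on all 5. Limma called these 2 genes. At an unadjusted p under 0.05 there were 1576, of which 17.1% were higher. That split was 65.3% with scaling over all probes, 29.0% with scaling to the median and 54.2% after quantile normalization. On the higher side none passed. Cul4a, the scaffold of a ubiquitin ligase, had a change of 7.63 ± 1.19 (at least 44.9-fold, adjusted p = 0.116). Mertk, a receptor for apoptotic cells, had one of 7.26 ± 1.53 (at least 33.0-fold, adjusted p = 0.489). Znrd1 (6.59 ± 1.48, adjusted p = 0.538), Slc9a3r2 (2.96 ± 0.69, 0.538) and Jarid2 (2.89 ± 0.72, 0.569) followed. Lower without passing were Rpf2 (−6.12 ± 1.07, adjusted p = 0.224), Ryr1 (−4.78 ± 0.90, 0.326), the flap endonuclease gene Fen1 (−5.99 ± 1.24, 0.453) and Tmem97 (−4.32 ± 0.89, at least 6.89-fold, 0.453).

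The probes of Cul4a, Mertk and Znrd1 lie at chromosome 8, 13147326 to 13147385, chromosome 2, 128627867 to 128627924, and chromosome 17, 37091447 to 37094519. Those of Slc9a3r2 and Jarid2 lie at chromosome 17, 24777541 to 24777600, and chromosome 13, 45016247 to 45016306. Fen1 and Tmem97 were probed at chromosome 19, 10273675 to 10273734, and chromosome 11, 78355541 to 78355600. Day 10 array 5, on the slide of the day 30 arrays, had a signal of 9.05 for Znrd1, and the change of Znrd1 was 1.02 and that of Tmem97 −1.56 with slide as a block. A second probe of Slc9a3r2, detected on 2 day 10 arrays alone, had changes from control of 1.93 at day 10 and 0.04 at day 30. That of Cul4a had changes of 0.24 and −0.80, and that of Tmem97 −0.97 and −2.35. Blocked on slide, the change of Wdr55 was −7.39 (adjusted p = 0.211) and that of Gm1976 −3.81 (0.143). The slide of 1 day 10 and 5 day 30 arrays alone sets these blocked changes. A fit within it gave the same changes by design, so it is no second check. Limma called 0 genes in the series matrix values, 1 after normexp with quantile normalization and 4 when the 2 groups were fitted alone. The count of 2 genes was 8 without day 10 array 2 or 3, 5 without day 10 array 5 and 4 without day 30 array 1.

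From day 10 to day 30, 7 lists rose relative to all genes by camera. With an estimated correlation or by fry 0 were called, against 13 at an unadjusted p under 0.05. Ribosomal proteins shifted by 0.61 (66 genes, 63 above the all-gene median, adjusted p = 0.000305; adjusted p = 0.310 with an estimated correlation), with 0 members past an unadjusted 0.05. Conventional dendritic cell genes shifted by 1.37 (23 genes, 18 above, adjusted p = 0.00109; adjusted p = 0.0852 with an estimated correlation). The lineage factor gene Irf8 stood at 4.46 ± 1.79 and Clec9a at 3.46 ± 1.77. LXR targets shifted by 1.10 (15 genes, 12 above, adjusted p = 0.00399; adjusted p = 0.0852 with an estimated correlation). Mertk rose when adjusted over that list alone (adjusted p = 0.00453). Class I presentation shifted by 0.77 (20 genes, 17 above, adjusted p = 0.00399; adjusted p = 0.0852 with an estimated correlation). NF-kB and immediate early genes shifted by 0.52 (36 genes, 31 above, adjusted p = 0.00399; adjusted p = 0.269 with an estimated correlation). Interferon-stimulated genes shifted by 0.65 (29 genes, 20 above, adjusted p = 0.0468; adjusted p = 0.310 with an estimated correlation), with Oasl2 at 4.91 ± 1.90. Anti-inflammatory genes shifted by 0.30 with a median change of −0.14 (22 genes, 16 above, adjusted p = 0.0193; adjusted p = 0.0852 with an estimated correlation). Mertk rose over that list alone too (adjusted p = 0.00664), and 0 other members of the 7 lists did.

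Ccr2, lower at day 10, rose by 4.47 ± 1.23 from day 10 to day 30 over the monocyte and neutrophil list alone (adjusted p = 0.0236). With slide as a block, the 7 shifts were −0.29 for ribosomal proteins, 0.08 for dendritic cells, −0.38 for LXR targets, −0.17 for class I presentation and −0.76 for NF-kB and immediate early genes. They were 0.32 for interferon-stimulated genes and −0.36 for anti-inflammatory genes, and camera called 0 lists. A fit within the slide of 1 day 10 and 5 day 30 arrays gives the same gene changes by design, so it is no second check. The count of 7 lists was 1 without day 10 array 1, 4 without day 10 array 2, day 30 array 1 or day 30 array 5, 11 without day 30 array 2 or 4, and 13 without day 10 array 5 or day 30 array 3.

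The fixed panel held cytokines, costimulatory molecules and microbial sensors that act in T cell priming. Of its 30 genes 23 were tested, and Il6, Tnf, Itgb8, Il12b, Cx3cr1, Tlr4 and Tlr5 were too rarely detected. In each comparison limma called 0 over all genes and 0 when adjusted over the panel alone, while 2, 2 and 1 had an unadjusted p under 0.05. Il1b had log2 changes of 0.07 ± 0.39 at day 10 and 0.29 ± 0.39 at day 30. Il10 had 0.66 ± 0.52 and 0.37 ± 0.52. Il23a had −4.95 ± 1.77 (detected on 0 day 10 arrays, at least 11-fold between the measured means, adjusted p = 0.159 over the panel) and −3.75 ± 1.77. Cd86, the costimulatory ligand, stood at −3.65 ± 1.16 at day 10 (adjusted p = 0.159 over the panel) and at 3.66 ± 1.16 from day 10 to day 30 (adjusted p = 0.155). Tgfb1 stood at 4.56 ± 1.29 at day 30 (adjusted p = 0.0748 over the panel).

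Over the 3 groups, the moderated F test of limma called 4 genes: Bcar3 (adjusted p = 0.000886), Wdr55 (0.00436), Gm1976 (0.0142) and Gpnmb (0.0301). Of the genes called against control, Bcar3 was lower at both times. Independent lists of these sizes would share 4.21e-05 genes, a value that leaves out the shared controls. Of 100 simulations of unchanged groups against the same controls, 3 shared a gene called lower in both and 2 a gene called higher. Of the 3 higher genes at day 10 and the 1 at day 30, 0 were shared (0.000126 for independent lists). The log2 changes at day 10 and day 30 correlated over 23708 genes, which are not independent replicates, with r = 0.607 and a covariance of 1.48. Unchanged groups simulated against the same controls gave a mean r of 0.480 (range 0.123 to 0.742 in 100 simulations). Their mean covariance was 0.905, a difference of 0.577. The sign was shared by 70.5% of genes, against 64.8% in the simulations. With the controls split between the 2 comparisons, r was 0.221 or 0.208 and the covariance 0.739 or 0.688.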

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

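The tests of signal range, of Bcar3 and Gpnmb within a slide and of innate lymphoid against T cell genes, also with arrays left out, were chosen after the results were seen. Dixon's test, run on 132 groups of 5 values at its 95% critical value of 0.71, singled out 12 values that lay far from the other 4 of their group. Chance gives about 1 in 20, which is 6.6 here. In controls, array 1 had a log2 signal of 5.21 for Gpnmb (the others 1.44 to 1.69) and of 5.29 for Gm1976 (1.87 to 2.19). Control 3 had one of 9.42 for Stra6l (1.70 to 3.26). Among day 10 arrays, array 1 had a score of 0.86 for the intestinal macrophage list, relative to all genes on the array (2.33 to 2.64). It had a signal of 5.46 for Stoml1 (1.02 to 1.93). Day 10 array 2 stood at 5.67 for Ryr1 (9.51 to 10.9) and at 8.39 for Sod1 (the others up to 11.4). Day 10 array 5, the only one on the third slide, stood at 9.05 for Znrd1 (1.53 to 3.16) and at 5.72 for Gm1976 (8.07 to 9.01). Day 30 array 1 had a score of 1.83 for the innate lymphoid and NK cell list, relative to all genes on the array (−1.28 to −0.69). It had a signal of 6.24 for Areg (1.27 to 2.00). Day 30 array 2 stood at 5.43 for Fen1 (0.97 to 1.90).

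Day 30 differed from day 10 for 2 genes by limma and 7 lists by camera, by the test of that difference itself. With an estimated correlation 0 of the 7 lists were called, and with slide as a block 0 genes and 0 lists. The change was −7.30 for Wdr55 and −5.97 for Gm1976, against −7.39 (adjusted p = 0.211) and −3.81 (adjusted p = 0.143) with the block, an estimate that rests on 1 day 10 array. The shift was 0.61 for ribosomal proteins, 1.37 for conventional dendritic cells, 1.10 for LXR targets and 0.77 for class I presentation. It was 0.52 for NF-kB and immediate early genes, 0.30 for anti-inflammatory genes and 0.65 for interferon-stimulated genes. Of 100 splits of these 10 arrays, 31 gave at least 2 genes (highest other 33) and 28 at least 7 lists (highest other 20), so chance cannot be excluded for either count.

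The first pattern weighed is the 19 lists that rose and the 1 that fell at day 30, of which 12 were called with an estimated correlation too. Of 100 splits of the 10 arrays 2, the real one included, gave at least 20 lists. The highest other, which exchanged 1 control for 1 day 30 array, gave 21. The rarity of so high a count argues against chance, but a split other than the real one gave more lists, so chance is not excluded. A narrower or wider signal range on the arrays of one group is argued against as the whole source of the call for 13 of the 19 lists. These stayed called after quantile normalization, with a median shift that went from 1.17 to 0.773. Among the 13, ribosomal proteins, heat shock, insulin signalling and lipid uptake were not called by camera with an estimated correlation, at adjusted p = 0.0528, 0.0982, 0.0522 and 0.0982. The shift went from 0.91 to 0.40 for ribosomal proteins and from 0.89 to 0.43 for anti-inflammatory genes, so signal range stays open for much of it there. Signal range also stays open for the other 6, whose median shift went from 0.847 to 0.647. The change of their mean score, relative to the median of all genes on each array, went from 1.06 ± 0.342 to 0.576 ± 0.266 (SE). Slide stays open for all 19, since no slide held both groups. With slide as a block their median shift was 0.297 in place of 1.01. The change of their mean score, relative to the median of all genes on each array, was 0.406 ± 0.932 in place of 1.49 ± 0.493 (SE), a spread too wide to decide. The high-fat diet and the slide cannot be told apart for these lists.

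The second pattern is a small set of genes that were present on one diet and missing on the other. Bcar3, Col28a1, Pianp and 1 probe without a gene name (the last 2 chosen after their values were seen) were detected on all 5 controls and on 0 of the 10 high-fat diet arrays. The rarity of so high a count argues against random loss of transcripts in amplification as its whole cause. A split other than the real one gave more such genes, so random loss is not excluded. Of 100 splits into 5 and 10 arrays 2, the real one included, gave at least 4 such genes (highest other 5). For any single gene such loss stays open. Slide was not weighed for Col28a1, Pianp and the probe without a gene name. The Y chromosome genes Ddx3y, Eif2s3y and Uty of these male mice were detected on 14, 12 and 7 of 15 arrays. Slide is argued against for Bcar3 and Gpnmb at day 10: on the shared slide 4 controls had 7.35 or more for Bcar3 and 1.44 to 1.69 for Gpnmb, 4 day 10 arrays had 1.54 to 2.18 and 5.85 to 12.74, and the smaller ratio of the within-slide change to that over all arrays was 1.01. A response of Bcar3 to the diet is therefore a hypothesis to follow up, found and tested on the same data, while an effect of slide on the day 30 values stays open.

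The third pattern is the lower shift of innate lymphoid and NK cell genes at day 30, called at a preset correlation (adjusted p = 0.0110) and not with an estimated one (adjusted p = 0.105), for which fewer such cells in the sort may be a candidate explanation. The exclusion of CD19 and of the T cell receptor would remove B and T cells. Innate lymphoid cells would be removed only where they lack MHC class II. Of the 15 genes measured, 1 is on another list. The most abundant were Klrb1b (11.34 in controls, 8.36 at day 10 and 6.14 at day 30), Tbx21 (10.96, 10.22 and 10.25) and Areg (10.62, 7.31 and 2.54), and on the T cell list Cd6 (12.72, 12.37 and 12.78), Ctla4 (11.63, 8.81 and 9.08; day 30 change −2.54 ± 1.57, SE) and Cd4 (9.30, 9.32 and 8.90; −0.39 ± 0.55). The score of the list, relative to the median of all genes on each array, was −1.09 at day 30 relative to controls and that of T cells 0.07. Without that reference the mean log2 changes were −1.93 and −0.77. The difference between both scores did not pass (exact two-sided permutation p = 0.111), nor did that from the B cell score (−0.38, exact permutation p = 0.571). The difference from T cells was −1.52 without day 30 array 1 (exact permutation p = 0.0238), without which the innate lymphoid score stood at −1.66. It was −1.42 without day 30 array 4 (0.0476). The answer thus rests on single arrays, and a lower share of all lymphoid cells stays open, as does slide. A change in signal range is argued against as the source of the call at the preset correlation, since the list had an adjusted p = 0.00958 after quantile normalization, within 0.0007 to 0.426 over all alternatives.

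For the counts of genes, chance cannot be excluded. At day 10 the real count was 4, and 18 of 100 splits gave at least as many. The highest other gave 584, with controls 1, 3 and 5 and day 10 arrays 1 and 2 on one side, where 50.2% of probes were detected against 37.1% on the other. That split followed detection and points to a structure of the samples. With slide as a block 2 genes were called at day 10. Within the shared slide 12 were, of which 1, Gm1976, was among the 4. At day 30 the count was 2, and 30 splits gave at least as many (highest other 15). Among the 3 groups it was 4, and 21 splits gave at least as many (highest other 24). Chance cannot be excluded either for the 4 lists called at day 10 (41 splits, highest other 18).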

How the results depend on the processing

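Scaling over all probes, cyclic loess, the share of detected probes as a covariate, leaving out the 3 arrays farthest from the median detection, matched random lists and fry under other scalings were chosen after seeing the data. The probes used for the main scaling were likewise chosen after the share of detected probes was seen. Counts are given in the order day 10 minus control, day 30 minus control, day 30 minus day 10. Over all arrays they were 4, 2 and 2 genes, 4 genes by the F test, 0 of the panel in each and 4, 20 and 7 lists. Of 301, 293 and 302 values of named genes under alternatives, 263, 264 and 287 kept their direction and side of the threshold, 30, 17 and 5 lost the call, 8, 12 and 10 gained it and 0 reversed. Most named genes had no call to lose. The losses at day 10 were 6 of 30 values for Wdr55, 20 of 30 for Ryr1 and 4 of 30 for Bcar3. At day 30 they were 12 of 29 for Gpnmb and 5 of 29 for Bcar3, and between the times 5 of 30 for Wdr55. Of 134, 654 and 237 values of called lists, 106, 572 and 132 kept both, 28, 76 and 95 lost the call and 0, 6 and 10 reversed. Signal over background limits what can be tested: a gene detected in 1 group alone, such as Bcar3, drops out when a probe must be well above background on all 15 arrays.

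With unadjusted p, 1441, 2903 and 1576 genes passed and 2054 by the F test, which is what leaving out the adjustment gives. A minimum of 2-fold beside the adjusted p left the counts at 4, 2, 2 and 4. Normexp and quantile normalization gave 0, 0 and 1 genes, 1 by the F test, 1, 2 and 1 of the panel, and 8 lists at day 10 and 0 between the times. Quantile normalization alone gave 4 genes and 1 of the panel at day 30 and 0 lists between the times. No filter on dim probes gave 2 and 1 genes at day 10 and 30 and 12 lists at day 10. Probes well above background on all 15 arrays gave 0, 0 and 0 genes, 0 by the F test, and 10 lists at day 10 and 3 between the times. Under that filter the shift of intestinal macrophages at day 30 was −0.70 and that of interferon-stimulated genes between the times 0.0287, and both tests reversed. The mean over the probes of a gene gave 7 lists at day 10, and eBayes with trend and robust 2 genes and 8 lists at day 10 and 2 of the panel at day 30. With the 2 groups compared only, 0, 10 and 4 genes passed. Array weights gave 0 lists between the times. Series matrix values gave 1, 5 and 0 genes, of which 0 were called in the main fit, and 1 of the panel at day 10. They gave 8, 10 and 1 lists, and interferon-stimulated genes between the times reversed, with a shift of −0.0713. The cause of these changes was not tested.

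Slide as a fixed block gave 2, 0 and 0 genes, 2 by the F test and 0, 0 and 0 lists, and the correlation of the day 10 and day 30 changes was 0.516 in place of 0.607. With the controls split it was 0.221 or 0.208. In each value marked as reversed the direction of the test turned, and the number given is the shift. At day 30 the block reversed NF-kB and immediate early genes (−0.17), ribosomal proteins (−0.40), heat shock (−0.52), class I presentation (−0.62) and glycolysis (−0.29). Between the times it reversed ribosomal proteins (−0.29), LXR targets (−0.38) and NF-kB and immediate early genes (−0.76). Within one slide, which leaves fewer arrays, 12 genes and 0 lists passed for day 10 minus control. Of these genes 1, Gm1976, was called in the main fit. Between the times, the tests of the same 3 lists reversed within one slide, with shifts of −0.29, −0.38 and −0.76. By design these repeat the blocked values, so they are no second check. Class I presentation (−0.17) and anti-inflammatory genes (−0.36) had shifts below 0 as well, without a turn of their tests. Slide as a random block gave the same genes as the main setting and was not run for lists. The cause of the other changes was not tested.

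Scaling the 75th percentile over all probes gave 1 of the panel at day 30 and 1 list between the times. Cyclic loess normalization gave 1 gene and 1 of the panel at day 30, 7 genes by the F test and 0 lists between the times. The share of detected probes as a covariate gave 1 gene at day 30, 1 gene between the times and 0 lists there. Without the 3 arrays, 9, 8 and 7 genes passed, of which 2, 1 and 1 were called in the main fit. The F test called 12 genes there, and camera 13 lists at day 10 and 0 between the times. Ribosomal proteins (−0.0945) and NF-kB and immediate early genes (−0.35) reversed between the times. With an estimated correlation 0, 12 and 0 lists passed, and by fry 0, 7 and 0 (at day 30, 6 of the 20 and B cells and plasma cells). Fry called 0, 0 and 0 lists with scaling over all probes and 0, 9 and 0 with scaling to the median. It called 0, 11 and 0 after quantile normalization and 0, 9 and 0 after loess. Against matched random lists 18, 19 and 10 passed. The random lists draw genes independently, so they leave out the correlation between genes. At day 30 the 19 include antimicrobial peptides, not called by camera, and leave out glycolysis and inflammatory cytokines. The cause of the other changes was not tested. Of the 20 lists called at day 30, 20 stayed called with scaling to the median, 16 over all probes, 16 after normexp, 14 after quantile normalization, 14 after loess, 18 with the covariate and 20 without the 3 arrays.

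Leaving out each array in turn gave 2 to 7, 1 to 13 and 2 to 8 genes, 4 to 10 by the F test, 0 to 1, 0 to 1 and 0 to 0 of the panel, and 3 to 11, 17 to 21 and 1 to 13 lists. The F count of 4 was 8, 10 and 8 without controls 2, 4 and 5, 7 and 10 without day 10 arrays 1 and 2, and 8 and 7 without day 30 arrays 1 and 5. The panel count was 1 at day 10 without control 4, and 1 at day 30 without day 10 array 3 or day 30 array 3. Ryr1 lost its day 10 call in 10 of 15 such fits (adjusted p = 0.052 to 0.117), namely without controls 1, 2, 4 or 5, day 10 arrays 1, 3, 4 or 5 or day 30 arrays 3 or 4. Gpnmb lost its day 30 call in 7 (0.0519 to 0.117), without controls 2 or 3, day 10 array 1 or day 30 arrays 1 to 4, and gained one at day 10 without control 1 or day 10 array 4 (0.036 and 0.0136). Stra6l passed at both times without control 3 and S1pr1 without day 10 array 2. Areg passed at day 30 without day 10 array 4, Col28a1 at both times and Hat1 and Stoml1 at day 30 without control 5. Between the times Cul4a passed without control 2 or 3, Ryr1 without day 10 array 2, Znrd1 without day 10 array 5 and Rpf2 without day 30 array 3. Oxidative stress genes lost their day 10 call in 5 fits (adjusted p = 0.0501 to 0.194), without control 1, day 10 arrays 3, 4 or 5 or day 30 array 3. At day 30, glycolysis (adjusted p = 0.0547) and fatty acid oxidation (0.0505) lost theirs without control 1, innate lymphoid genes without control 4 (0.0657), and inflammatory cytokines without control 1 or day 30 arrays 1 or 5 (0.0736 to 0.172). Between the times interferon-stimulated genes lost theirs in 7 fits, NF-kB and anti-inflammatory genes in 4 each, LXR targets in 2 and ribosomal proteins and class I presentation in 1 each, and dendritic cell genes in 0.

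No pairing of the samples by replicate number was seen, though a weak one is not excluded. Of 15 same-numbered pairs of arrays, 1 had a correlation of deviations above 0.1 (range −0.143 to 0.197), and 3 of 15 arrays correlated best with their own number. With the replicate block 0, 0 and 0 genes passed, 0 by the F test, 0, 1 and 0 of the panel and 3, 20 and 7 lists. The correlation of changes was 0.607, a value this block cannot alter, since each group holds every replicate number.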

Other observations

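The only explanation weighed below rests on tests chosen after the result was seen, as was fry under other scalings, and the genes named were chosen after their values were seen. The B cell and plasma cell list was called lower at day 30 by fry (adjusted p = 0.0206; 0.0316 after quantile normalization and 0.580 with scaling over all probes) and not by camera (0.0614), and the genes given here did not pass over all genes. The immunoglobulin heavy chain transcript Igh-VJ558, among the brightest on the arrays, had a log2 signal of 16.77 in controls, 15.86 at day 10 and 15.83 at day 30, with changes of −0.90 ± 0.41 and −0.94 ± 0.41 (SE). Jchain had changes of −1.39 ± 0.49 and −1.33 ± 0.49, while Cd22, a receptor of mature B cells, had signals of 13.08, 12.95 and 12.79. Derl3, which takes part in the degradation of misfolded secretory proteins, was detected on 3, 1 and 1 arrays and had a day 30 change of −4.04 ± 1.41. Xbp1, the transcription factor of secretory cells, had one of −3.23 ± 1.37 and Sel1l, of the same degradation pathway, one of −1.62 ± 0.81, both within the unfolded protein response list, which was not called (shift 0.28, adjusted p = 0.403, 16 of 25 members above the all-gene median). The chaperone gene Pdia6, of that list as well, had one of 2.31 ± 1.11.

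Markers of plasmacytoid dendritic cells were not called by camera. Their shift was −0.92 at day 10 (9 genes, 1 above the all-gene median, adjusted p = 0.0886; 0.0255 unadjusted) and −0.41 at day 30 (3 above, adjusted p = 0.212). Siglech, their surface marker, had a signal of 14.51 in controls, 14.16 at day 10 and 14.15 at day 30. Ccr9, a receptor for homing to the small intestine, had means of 9.75, 7.72 and 4.91 (day 30 change −4.84 ± 1.58, SE), and Tcf4, the lineage factor, means of 11.55, 9.02 and 9.32 (−2.23 ± 1.12). Among interferon-stimulated genes at day 30, the change was 5.35 ± 1.90 for Oasl2, −2.78 ± 2.01 for Ifit3 and −2.20 ± 0.62 for Zbp1, a sensor of nucleic acids. Irf8, the lineage factor of a class of dendritic cells, had means of 9.50, 5.73 and 10.19 in controls, at day 10 and at day 30. None of these genes passed over all genes.

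One hypothesis is that fewer antibody-secreting and innate lymphoid cells entered the sort on the high-fat diet. The list scores, relative to the median of all genes on each array, changed from controls to day 30. The change was −0.71 for B cells and plasma cells (exact two-sided permutation p = 0.206) and −1.09 for innate lymphoid and NK cells (exact p = 0.159). That of T cells was 0.07 (exact p = 0.905), and the innate lymphoid score less that of T cells had an exact p = 0.111. Without the reference to all genes, the mean log2 changes were −1.55 for B cell, −1.93 for innate lymphoid and −0.77 for T cell genes. The permutation tests neither bear the hypothesis out nor exclude it. Fry called both lists lower at day 30 under the main scaling (adjusted p = 0.0206 each) and after quantile normalization (0.0340 for innate lymphoid and 0.0316 for B cell genes). With scaling over all probes it called neither (0.209 and 0.580), and camera called the innate lymphoid list alone (adjusted p = 0.0110; adjusted p = 0.105 with an estimated correlation). Of the 5 permutation comparisons made, each over 252 divisions, the other was the innate lymphoid score less that of B cells and plasma cells. It changed by −0.38 (exact two-sided permutation p = 0.571). Of the genes measured, 2 of 20 on the B cell list and 0 on the T cell list are also on another list. The gate on CD19 would remove B cells, though antibody-secreting cells can lack CD19. A count of such cells by flow cytometry in the same sort would test it directly.

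Enterocytes lie beside the sorted tissue and would be removed by the gate unless they carry MHC class II, as they can in the small intestine. Of their most abundant genes, Dgat1 had log2 signals of 13.53, 13.99 and 14.01 in controls, at day 10 and at day 30, Anpep at 8.53, 10.19 and 10.61 and Cldn7 at 8.52, 8.05 and 8.02. Of the 14 genes measured 1 is on another list. Genes of the Y chromosome, present in all these male mice, varied between arrays: Ddx3y was detected on 14 of 15 arrays (3.49 to 11.3), Eif2s3y on 12 (0.94 to 12.8) and Uty on 7 (1.45 to 11.2).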
